A study of Brassica rapa subsp. pekinensis with 6 samples.

How the data were processed

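RNA sequencing of flower buds from a Chinese cabbage male sterile line was analysed, with 3 fertile and 3 sterile libraries. The genotype label of each sample gave its group, and the series design describes the replicates as biological. Each table column was matched to its sample through the sample title.

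Both tables used are of the whole series and were deposited by the authors, with 12 columns used. The first holds raw read counts per gene, per the file headers, and its values are whole numbers with a different sum in every library. The second holds RPKM, reads scaled to the length of the gene model and to the counted reads of the library, as deposited by the authors. Dividing count by RPKM in 26797 genes with over 20 counts in every library returned one length per gene to within 1 part in 10000, with 1 exception whose lengths differed by up to 1.18 times. The RPKM values were therefore the same counts divided by model length and by the sum of the count column. TopHat2 2.0.9 and Bowtie2 2.0.6 are named in the submitters' processing notes, with no role given. The read counter, its strand setting, the genome build and the annotation are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical copies may have been split, which matters in a genome with many duplicated genes.

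The count table lists 43354 identifiers, of which 41019 begin with Bra and 2335 have the form of Novel02088. How these non-Bra models were made is not given in the sources used here. All Bra model lengths recovered from the tables were multiples of 3 (100%), so they are coding lengths. Of the lengths of non-Bra models 33.9% were, the share of a length without a reading frame. The tables disagree in a few identifiers: 2 are listed more than once in the RPKM table, 3 of the count table are missing from it and 1 is found only there. Rows of the RPKM table were kept as deposited, and those identifiers were left out where the tables were joined. Every row of both tables carries an identifier, and none is a total or a class of unassigned reads.

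Neither table pairs identifiers with gene names. A RefSeq gene table of another assembly (CAAS_Brap_v3.01, 51589 genes) was used for names alone and matched 1 identifier. The 18 gene lists fixed before the data were examined, which covered tapetum, pollen wall, meiosis, other floral organs and RNA quality, were therefore not tested, and neither was the planned test by chromosome. No coordinates are printed for the same reason.

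Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 33150, libraries were scaled by TMM (trimmed mean of M values), and the quasi-likelihood test (glmQLFit and glmQLFTest) compared sterile with fertile without a term for replicate number. Benjamini-Hochberg adjusted p under 0.05 was the threshold, alone or with a change of at least 2-fold. All fold changes are sterile relative to fertile. CPM values in the text are counts scaled to the library total with TMM factors; raw CPM uses the total alone. The standard error of a log2 fold change is the fold change divided by the square root of its F statistic, an approximation. RPKM values were tested with limma 3.58.1 (trend) on log2(RPKM + 1), keeping genes at RPKM of at least 1 in 3 libraries, so fold changes of low genes are understated there. When a library was left out, as many libraries as the smaller group held were asked for instead of 3. A gene was counted as detected in one group only at 1 raw CPM or more in all 3 of its libraries and 0 counts in the other 3. Where a gene had 0 counts in a group, the fold is a lower bound against a floor of 3 counts summed over that group's libraries.

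Counts for the 3 against 3 comparison were simulated for the 33150 tested genes with the observed means, library sizes and trended dispersions (smoothed over abundance). The edgeR test recovered 94% of 50 genes changed 2-fold, 80% of 50 changed 1.5-fold and 14% of 50 changed 1.2-fold. It called 8 unchanged genes among 150 calls. Few genes were changed in the simulation, and in random directions. The threshold on adjusted p was therefore stricter there than in the data, where 20712 genes passed. The recovered shares do not carry over to the data, above all for small changes, and a shift in one direction was not simulated. The limma test on simulated RPKM of 29669 genes recovered 95.7% of 47 genes changed 2-fold and 9.3% of 43 changed 1.2-fold, with 11 unchanged genes among 143 calls.

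Totals ran from 27637426 to 35564895 counts per library, so 3 counts correspond to between 0.0844 and 0.109 raw CPM. Such floors cover counting error alone; molecular identifiers are not mentioned in the sources used here. The intervals of odds ratios and of the weighted excess are across genes, which are not independent replicates. With 3 libraries per group an exact permutation test cannot give a two-sided p below 0.10. The correlations of deviations from the group means between same-numbered fertile and sterile libraries were 0.019, -0.029 and 0.083, so replicate numbers were not treated as pairs.

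Genes named in the text were fixed by rule before the data were examined: since identifiers have no names, the 2 largest falls and the 2 largest rises among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. The 1 identifier with a name was added after its values were seen. Alternatives were RLE, upper-quartile and library-size-only scaling, other low-count filters, DESeq2 1.42.0, limma-voom, edgeR's glmTreat, a replicate block, other pseudocounts, other detection limits, and leaving out each library in turn. Thinning to equal depth and centring of fold changes were added after seeing the data.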

Results

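The transcriptome of flower buds was compared between fertile and sterile plants of a Chinese cabbage line (Brassica rapa subsp. pekinensis) whose male sterility is inherited through several alleles. Male sterile plants form no functional pollen. Read counts per gene were available for 3 fertile and 3 sterile libraries. Fertile libraries held 27637426, 28255637 and 35564895 counts, and sterile libraries held 31893913, 32313032 and 33615379. At least 1 count was found for 37740, 37637 and 38132 genes in fertile buds and for 36657, 36784 and 36894 genes in sterile buds. After thinning to the smallest total, the fertile libraries still showed more genes (37597 to 37740) than the sterile ones (36403 to 36569).

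Libraries of one group were close to each other and the groups were far apart. Across all genes, which are not independent replicates, Pearson's r of log2 (raw CPM + 1) was 0.998 for each pair within a group and 0.889 to 0.893 between groups. The first principal component held 97.4% of the variance and separated fertile from sterile. Pairs within a group differed by 2.84 to 4.55 times the variance that sampling alone gives, so no library was a second sequencing of another within sampling noise. Separate preparations of one RNA sample are not excluded by this. The biological coefficient of variation was 5.26%, and at this spread small changes pass a test.

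The main comparison asked which genes differ in abundance between sterile and fertile buds. Sterile buds had less of 11027 genes and more of 9685, out of 33150 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). Of these 20712 genes, 13722 changed by less than 2-fold. The groups' libraries did not overlap for 66.6% of genes tested, where chance gives 10%. Among genes changed at least 2-fold, 4996 fell and 1994 rose, so 71.5% of the larger changes were falls. Scaling to library size alone shifted the median log2 fold change of all genes from 0.00 to 0.31, and the falls then made up 25.9% of all calls and 57.2% of those of at least 2-fold. With upper-quartile scaling the median was 0.19 and the falls made up 33.2% of all calls.

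**Figure D1:**
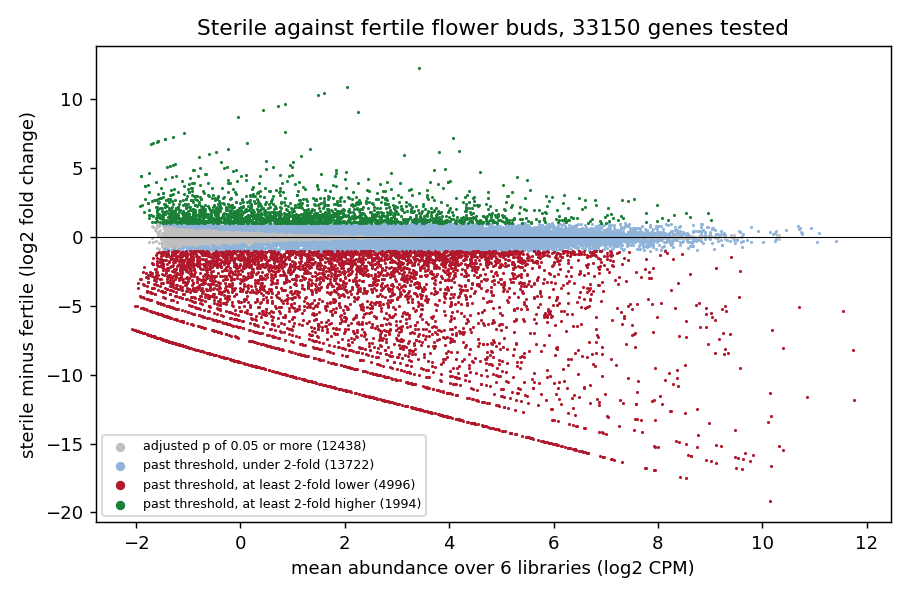
Log2 fold change of sterile against fertile buds (vertical axis) by mean abundance in log2 CPM (horizontal axis) for the 33150 genes tested, coloured by call. The 4996 genes at least 2-fold lower reach much larger changes than the 1994 at least 2-fold higher, also among the most abundant genes; the diagonal lines at the bottom are genes with 0 or few counts in sterile buds, whose fitted values depend on the prior count.

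The falls and the rises differed in size. Changes of 2-fold to 4-fold were about as many in each direction, with 1471 genes lower and 1435 higher in sterile buds, although library-size scaling turned this into 1115 lower and 2475 higher. From 4-fold to 10-fold, 928 genes were lower and 415 higher. From 10-fold up, 2597 genes were lower and 144 higher. Above 100-fold the fitted counts were 1336 lower and 21 higher, and 1139 lower and 8 higher when genes with 0 counts in a group were set at their lower bound.

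**Figure D2:**
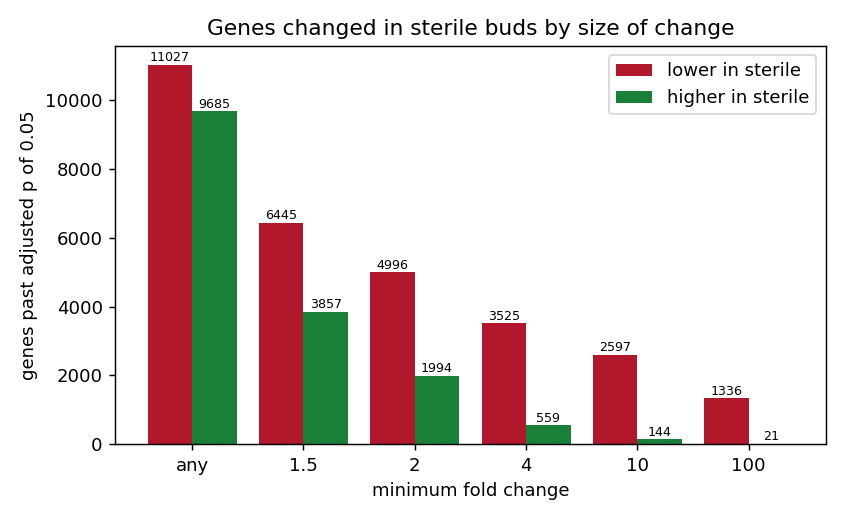
Number of genes past the threshold (vertical axis) that were lower or higher in sterile buds at increasing minimum fold changes (horizontal axis). With TMM scaling the direction was nearly balanced for changes of any size, with 11027 lower and 9685 higher. It lay at 2597 lower against 144 higher from 10-fold up. The balance depended on scaling: with library size alone, 6854 genes were lower and 19608 higher for changes of any size.

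The genes that fell included the most abundant ones of fertile buds. Of the 100 most abundant genes in fertile buds, each at 733.8 CPM or more, 79 fell in sterile buds, 15 rose and 6 did not pass the threshold. In 62 of them the fall was at least 10-fold, and in 46 at least 100-fold. Their median log2 fold change was -5.92. Of the 10 most abundant, all 10 fell, 8 of them by at least 10-fold. The 100 most abundant genes of sterile buds changed much less: 54 were higher, 18 lower and 28 not past the threshold, none fell by as much as 2-fold, and their median log2 fold change was 0.17. With library-size scaling the counts were 66 lower and 22 higher for the fertile list, and 2 lower and 83 higher for the sterile list. The lists shared 35 genes. Ranking by abundance in one group favours genes higher in that group, so few falls can appear in the sterile list. The like comparison is 65 falls of at least 2-fold in the fertile list against 4 rises of at least 2-fold in the sterile list, with TMM scaling.

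Genes at least 10-fold lower in sterile buds took 18.15% ± 0.252 (SD, n = 3) of the counts of fertile libraries and 0.244% ± 0.0126 (SD, n = 3) of those of sterile libraries. The 1994 genes at least 2-fold higher made up 0.803% ± 0.00977 (SD, n = 3) of fertile counts and 3.03% ± 0.0333 (SD, n = 3) of sterile counts. These classes were chosen on the same libraries, so the shares describe their weight and are not a separate test. Independent of any call, the 100 most abundant genes of each library held 13.2% ± 0.136 (SD, n = 3) of fertile counts and 9.43% ± 0.218 (SD, n = 3) of sterile counts. The difference of -3.82 percentage points had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows.

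**Figure D3:**
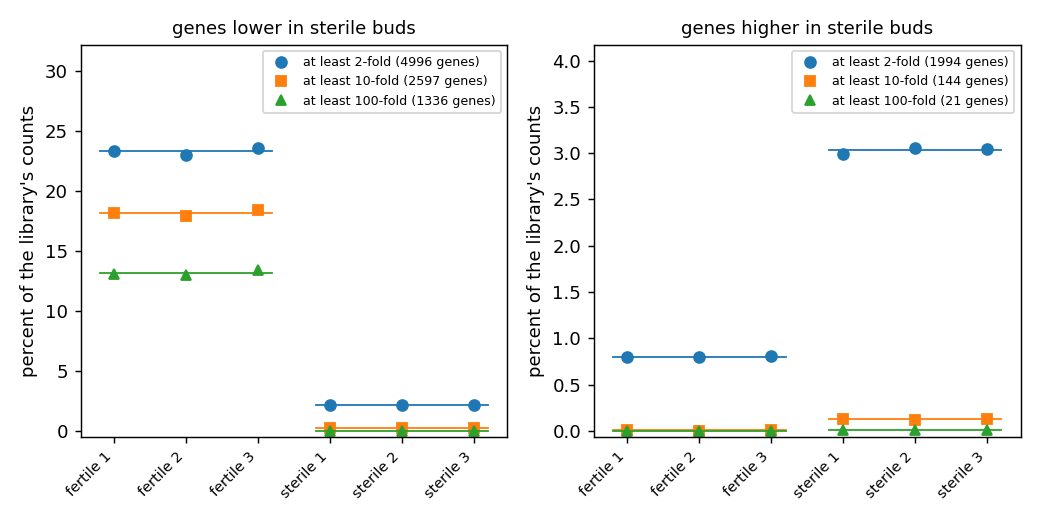
Percent of each library's counts (vertical axes, with different ranges) taken by genes lower (left) or higher (right) in sterile buds by at least 2-fold, 10-fold or 100-fold, with points for the 6 libraries and lines for group means. Genes at least 10-fold lower took 18.15% of fertile counts and 0.244% of sterile counts.

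Detection in one group only was far more common in fertile buds. In fertile buds 381 genes were at 1 raw CPM or more in every library with no count in any sterile library, and 211 of them had a mean of at least 10 raw CPM. Together they held 1.86% ± 0.116 (SD, n = 3) of fertile counts. The opposite pattern was found for 8 genes, 1 of which, Novel02088, had a mean of at least 10 raw CPM. All 381 and all 8 passed the edgeR threshold, which their selection on the same libraries made nearly certain, so this is no separate evidence. A count of 0 over the 97822324 sterile counts allows up to 0.0307 raw CPM. The number also depends on how absence is set: with fewer than 3 counts allowed in the other group, 726 genes were found in fertile buds and 15 in sterile buds.

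The 2 falls with the largest fitted values were from high abundance to no reads. Fitted values of genes at 0 counts depend on the prior count. With group means below 3 counts set at that floor, Bra014410 ranked 2 and Bra018841 ranked 23 among the falls, behind genes with a few sterile reads. Bra014410, with a coding length of 1728 nt, stood at 2266 ± 23.8 CPM (SD, n = 3) in fertile buds and had 0 counts in all sterile libraries, at least 82106-fold lower (edgeR adjusted p = 1.3e-22). Bra018841, with a coding length of 1551 nt, stood at 744.8 ± 24.3 CPM (SD, n = 3) in fertile buds and also had 0 counts in sterile buds, at least 26987-fold lower (edgeR adjusted p = 2.6e-22). The 2 largest rises, which also ranked 1 and 2 at that floor, started from little or nothing. Novel02088, a model of 1334 nt, had 0 counts in fertile buds and 19.7 ± 0.75 CPM (SD, n = 3) in sterile buds, at least 541-fold higher (edgeR adjusted p = 1.6e-17). Bra027075, with a coding length of 363 nt, rose from 0.225 ± 0.085 to 31.7 ± 3.65 CPM (SD, n = 3 each), a log2 fold change of 7.15 ± 0.17 (SE; edgeR adjusted p = 1.3e-18). The tables give neither names nor positions for these genes, and whether they have near-identical copies is not known here.

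A name was available for Bra000116: the RefSeq table gives both Bra000116 and SWEET9 as synonyms of a gene whose symbol there is LOC103857843. SWEET proteins are sugar transporters, and SWEET9 is known for sucrose export in nectaries. It had 4.02 ± 0.47 CPM in fertile buds and 7.92 ± 4.47 CPM in sterile buds (SD, n = 3 each), a log2 fold change of 0.98 ± 0.27 (SE; edgeR adjusted p = 0.0037). The sterile libraries stood at 4.39, 6.44 and 12.9 CPM. Without sterile replicate 3 the log2 fold change was 0.42 (edgeR adjusted p = 0.020), and with DESeq2 on all libraries SWEET9 was not past the threshold (adjusted p = 0.077).

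Models outside the Bra set (identifiers of the form Novel02088) fell more often than Bra models. Of 1974 such models tested, 651 (32.98%) were at least 2-fold lower in sterile buds, against 4345 of 31176 Bra models (13.9%). The odds ratio was 3.04 (95% interval 2.75 to 3.36, two-sided Fisher's exact test across genes, p = 1.7e-94, adjusted over 2 tests 3.5e-94). At least 2-fold rises were found for 131 of them (6.64%) and 1863 Bra models (5.98%), with an odds ratio of 1.12 (0.924 to 1.34, Fisher's exact p = 0.24). Bra models weighted to the abundance of the non-Bra models were at least 2-fold lower in 19.9% and at least 2-fold higher in 11.1%, so at like abundance the non-Bra share was above the Bra share for falls and below it for rises. The non-Bra models had a median of 1.91 CPM and Bra models one of 12.003 CPM. Non-Bra models held 2.63% to 2.9% of counts in fertile libraries and 2.16% to 2.31% in sterile libraries.

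The shortest Bra models changed more often than the longest in both directions, without a steady trend for falls. Of the 6296 shortest by coding length (150 to 594 nt), 15.9% were at least 2-fold lower and 7.61% at least 2-fold higher. Of the 6218 longest (1779 to 16227 nt), 746 were at least 2-fold lower and 208 (3.35%) at least 2-fold higher. In the classes between, in order of length, 12.7%, 14.5% and 14.5% were at least 2-fold lower and 7.02%, 6.64% and 5.24% at least 2-fold higher. The odds ratio of the shortest to the longest models was 1.39 (95% interval 1.25 to 1.54) for falls and 2.38 (2.01 to 2.82) for rises, with Fisher's exact p adjusted over 2 tests of 2.5e-10 and 8.3e-26. The median log2 fold change lay between -0.01 and 0.03 in each of 5 classes of length. Median abundance rose with length, from 2.89 log2 CPM in the shortest class to 4.31 in the longest.

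The deposited RPKM values, tested with limma on log2(RPKM + 1), called 24451 of 30204 genes, 18440 higher and 6011 lower in sterile buds. These values are scaled to library size, and the median log2 fold change was 0.27. Of changes of at least 2-fold on this scale, 3276 were lower and 1572 higher. The rises depended on the pseudocount, with 3621 lower and 2518 higher at 0.1, and 3662 lower and 2665 higher at 0.01. Of 30134 genes tested in both tables, 15024 were called in the same direction by both tests and 2.95% of those called by both were in opposite directions. That share leaves out genes called by 1 test alone. The log2 fold changes had a Pearson r of 0.934 across genes. Both tests rest on the same counts, so their likeness is no separate evidence.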

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

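Thinning to equal depth and centring of fold changes were chosen after seeing the data, and the other alternatives before. The number of genes past the threshold stayed within 1.5 times 20712 under every alternative run (18883 with DESeq2 to 26462 with library size alone), and those of at least 2-fold stayed within 1.5 times 6990. The direction of calls depended on scaling: genes higher in sterile buds numbered 16076 with upper-quartile factors and 19608 with library size alone, and genes lower 6854 with library size alone. For changes of at least 2-fold, 3263 were higher with library size alone and 1212 with glmTreat, which tests against a 2-fold change and so asks for more. In the first case the median log2 fold change was 0.31. Centring those fold changes on their median, with the adjusted p of the uncentred fit kept, gave 4981 lower and 1994 higher. Centring removes such a shift by construction, so this describes its size and is not a test of its cause. Leaving out each library in turn gave 19146 to 20143 genes past the threshold (8715 to 9294 higher, 10431 to 10870 lower), 7180 to 7290 of at least 2-fold (2028 to 2144 higher, 5051 to 5215 lower), 381 to 483 genes in fertile buds only, 8 to 11 in sterile buds only, -3.91 to -3.70 percentage points for the 100 most abundant genes, and 23623 to 24012 genes in RPKM. The number of genes in one group only rose to 726 for fertile and 15 for sterile buds with fewer than 3 counts allowed in the other group, and was 3 for sterile buds at 5 CPM, Novel02088 among them. The share of counts in the 10, 50 and 500 most abundant genes differed by -1.28, -2.81 and -4.58 percentage points. The cause of these last differences was not tested beyond the wider or narrower definition. A replicate block gave 21212 genes, 6994 of them at least 2-fold, and 24593 in RPKM; same-numbered libraries did not deviate together (correlations of 0.019, -0.029 and 0.083, and not every library correlated best with its own number), so the numbers were not taken as pairs. The block changed no call of a named gene. The log2 fold change of SWEET9 (Bra000116) was 0.97 with DESeq2, where the call ended at an adjusted p of 0.077 (range over its alternatives 1.4e-05 to 0.077), and 0.42 to 1.26 when a library was left out. The other named genes kept direction and call in all alternatives examined for them. Upper-quartile scaling, the stricter low-count filter, thinning and glmTreat were not examined for named genes. List tests and the test by chromosome, with their alternatives, were not run, since identifiers have no names or positions. Depth limits genes in one group only: a count of 0 over one group allows up to 0.0307 or 0.0328 CPM.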

Other observations

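The scalings and the count of splits were chosen before the data were examined. Thinning, centring, leaving out the 500 most abundant genes, the weighting by abundance and the tests on identifier numbers were chosen after the main result was seen, and the tests of scaling on 10-fold changes and of models built from both groups' reads after the tested values themselves were seen.

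Genes that carry neighbouring identifier numbers tended to change together. Among 24758 pairs of tested Bra genes with consecutive numbers, Spearman's rho of the log2 fold changes was 0.061, above all 1000 permutations, whose highest value was 0.022. At a distance of 2 numbers rho was 0.026, also above the highest permuted value of 0.019, and at 5 numbers it was 0.002, within the permuted range. Genes at least 10-fold lower in sterile buds formed 230 consecutive pairs, against a permuted mean of 117.4 and a permuted maximum of 151. Genes at least 2-fold higher formed 151 pairs, against a permuted mean of 88.8 and a maximum of 118.

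These pairs may reflect tandem copies or neighbouring genes with a common pattern, on the untested assumption that numbers follow genome order. Whether a single linked stretch is the whole cause was not decided. Without the 5 windows of 100 numbers richest in changed genes, rho was 0.060. That left 24460 of 24758 pairs, so rho could hardly have fallen. No window held more changed genes than the highest permuted maximum (27 against 35). This compared numbers of changed genes, not their shares of the genes tested in each window. The bar was also the highest of all permuted maxima, so a lesser excess within a window is not excluded. Reads shared between near-identical copies stay open. Leaving out pairs whose lengths differ by 10% or less lowered rho to 0.047, which met the bound of 0.05 set for that explanation but still lay above all permuted values. No sequence was used here to tell copies apart.

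The second pattern is the excess of large falls over large rises in sterile buds. A difference in depth is argued against, since the ratio of genes at least 2-fold lower to genes at least 2-fold higher was 2.51 after thinning. Without the 500 most abundant genes, left out before scaling, it was 2.48, with 4920 genes lower and 1984 higher. This decides nothing about their number, since most of the 500 were not among the 4996 falls. Even 500 falls fewer could not by number alone have brought the ratio to 1. Scaling stays open for 2-fold changes, where the lowest ratio was 1.34, with library size alone. For 10-fold changes the ratio was 12.9 or more under every scaling and centring run. The median log2 fold change reached 0.31 at most, with library size alone, so only scaling shifts of about that size are argued against. A candidate explanation in the design is that sterile buds lack cells or stages that fertile buds have, and another is a change of transcription within cells present in both; neither was tested, because marker genes could not be identified.

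The third pattern is the more frequent fall of models outside the Bra set. Lower abundance is argued against as the whole cause: against Bra models weighted to the same abundance, the excess of models at least 2-fold lower was 13.1 percentage points (95% bootstrap interval over genes 10.9 to 15.1), after 19.0 unweighted. Models built from both groups' reads might favour genes strong in either group, but the odds ratio of a rise was 1.12, with an upper limit of 1.34, and Bra models weighted to the same abundance rose more often (11.1% against 6.64%). Models built mainly from fertile reads would give this pattern, and how they were built is not given in the sources used here, so no biological explanation was tested.

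In the other splits of the 6 libraries into 3 and 3, the real split alone (1 of 10) gave as many genes as observed: 20712 past the threshold, 6990 of at least 2-fold and 24451 in RPKM, with 0 in the highest other split each time. With 10 splits a share under 0.05 cannot be reached. Every other split mixed fertile and sterile libraries, so the difference between them entered the spread within each group. Few or no calls could arise there, and the values of 0 are no separate evidence.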
